A study of Homo sapiens with 6 samples.

How the data were processed

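Messenger RNA was measured by bulk RNA sequencing in SK-N-BE(2) cells, a human neuroblastoma line with amplified MYCN. The labels gave 3 groups of 2 libraries each. One group received a control short hairpin RNA (shControl), and the other groups received hairpin 1 or hairpin 2 against BCAT1. BCAT1 is the cytosolic enzyme that transaminates branched-chain amino acids. Total RNA was extracted with TRIzol and libraries were made with a TruSeq RNA kit, per the labels' protocols. HISAT2 version 2.2.0, StringTie and the genome build hg38 are named in the submitters' processing notes. The StringTie version, the annotation release, the counting options and whether counting used strand are not given in the sources used here.

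The deposited table held whole-number counts per Ensembl gene, not normalized, with a column per library and 64252 rows. Column names were matched to the sample labels, and every column was used. Total counts per library were 39321388 and 38588163 for shControl, 38528990 and 32333416 for hairpin 1, and 39028395 and 37637699 for hairpin 2. Gene symbols came from a table of Ensembl IDs, which held 56105 of the IDs and lacked 8147, and 40995 rows had a symbol. Coordinates and exon overlaps came from GENCODE release 29 on hg38.

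Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by group (minimum count 10), which kept 18734 genes, 16052 of them with a symbol and 1368 not in the name table. Libraries were scaled with TMM, whose factors ran from 0.96 to 1.035. The quasi-likelihood model (glmQLFit and glmQLFTest) had a term per group and no other term. All 6 libraries shared a single estimate of the spread, which left 3 residual degrees of freedom. Contrasts were the mean of both hairpins against control, each hairpin against control, and hairpin 2 against hairpin 1. All tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM, counts scaled to library size with TMM, as mean ± SD of the 2 libraries of a group. A gene at 0 in a group was given a floor of 3 counts per library. Such floors cover counting error only.

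Gene lists of textbook pathways and cell type markers were tested with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Of 44 lists, 42 had at least 5 tested members. Adjusted p-values for lists were computed over the lists tested in each comparison. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named BCAT1 and MYCN always. It then took the 10 largest rises and the 10 largest falls of the main comparison, and the 5 largest of each for a single hairpin and for the hairpin difference. Such genes needed an adjusted p under 0.05, a symbol, a mean CPM of at least 5, and every library of the groups compared on the same side. For each list that passed in any comparison, the 3 members with the smallest p over both hairpins against control were named. In the other comparisons these need not be the leading members of their list. A gene that this rule names is not reported here. XIST and Y-linked genes were left out.

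Replicates of each group were compared before they were averaged. The mean chi-square per gene between replicates was 8.6, 6.68 and 5.86 for shControl, hairpin 1 and hairpin 2, where sampling noise alone gives 1, so no library was a second copy of another. Correlations of log2 CPM across genes, which are not independent replicates, were 0.988 to 0.989 within groups and 0.968 to 0.974 between groups. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The common biological coefficient of variation was 8.7%.

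The main test was tested on simulated counts in which 200 genes changed. In the simulated comparison of both hairpins with control, over 18360 genes, edgeR recovered 58.8% of the genes changed by 0.5 on the log2 scale, 93.9% of those changed by 1 and 98.5% of those changed by 2. Of its 184 calls there, 9.2% were false. With a GC trend added to the simulated knockdown libraries, 94.6% of 2858 calls were false without correction, and 3.3% of 153 after correction for GC content and length. Both hairpins were compared with the same control libraries. So 20 simulated sets of unchanged groups gave the overlap and covariance that shared controls produce when no gene changes and libraries vary only as replicates do.

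The alternatives were size factors of the kind DESeq2 uses (RLE), no low-count filter, a stricter filter (CPM of at least 1), DESeq2 1.42.0, limma-voom, a term for the replicate number, only the groups compared, each library left out in turn, a fold threshold of 1.5, and summed rows of a shared symbol. For the lists, an estimated correlation and fry were also run. Further alternatives were chosen after seeing the data. They were a per-library correction for GC content and transcript length (a spline with 5 degrees of freedom over 13829 protein-coding genes), the same genes without correction, rows with a symbol only, and genes whose annotated 3′ UTR holds neither of the hexamers GCAGTA and TGCCCA. The scan of 3′ UTR heptamers used the 11495 genes with a mean CPM of at least 2 and an annotated 3′ UTR of at least 50 nt, 16352 heptamers and 200 permutations. Shares of genes with and without the hexamers were taken over all 13666 tested genes with such a 3′ UTR. Scripts outside R used Python 3.11.15 with numpy 2.4.6. N-Myc protein, BCAT1 protein and metabolites were not analysed here.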

Results

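Transcripts of SK-N-BE(2) neuroblastoma cells were counted in 6 libraries, 2 with a control hairpin, 2 with BCAT1 hairpin 1 and 2 with BCAT1 hairpin 2. The series title names N-Myc stabilization by BCAT1 in neuroblastoma with amplified MYCN, and these data hold its transcript side. Total counts ran from 32333416 in the shallowest library, replicate 2 of hairpin 1, to 39321388 in replicate 1 of the control. Genes with at least 1 count numbered 25342 to 26716 per library. Libraries separated by group, with the first principal component holding 39.7% of the variance and the second 33.8%. Mitochondrially encoded mRNAs took 2.18% to 2.56% of counts.

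BCAT1 mRNA (ENSG00000060982, chromosome 12, 24810022 to 24949459, minus strand, hg38) was lower in all 4 knockdown libraries than in both controls. Control libraries held 459 and 475 CPM, hairpin 1 libraries 55.8 and 55.3 CPM, and hairpin 2 libraries 116 and 111 CPM. The counts behind these levels were 17348 and 17597, then 2162 and 1795, then 4664 and 4325. With hairpin 1 BCAT1 fell 8.41-fold (log2 fold change −3.07, SE 0.04, edgeR adjusted p = 1.8e-08), and with hairpin 2 it fell 4.12-fold (−2.04, SE 0.04, edgeR adjusted p = 1.3e-07). The knockdown was deeper with hairpin 1, by 1.03 on the log2 scale (SE 0.04, edgeR adjusted p = 7.3e-07). Exons of BCAT1 overlap AC023796.2, AC026310.2 and AC026310.3, so a part of its reads is uncertain.

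MYCN mRNA (ENSG00000134323, chromosome 2, 15940564 to 15947007, plus strand, hg38), which encodes N-Myc, stayed among the abundant transcripts. It stood at 2260 ± 14 CPM in control cells (SD, n = 2), 1820 ± 5.1 CPM with hairpin 1 and 1760 ± 80 CPM with hairpin 2. Against control, MYCN fell 1.26-fold over both hairpins (log2 fold change −0.34, SE 0.04, edgeR adjusted p = 9.5e-05), and the hairpins differed by −0.05 (SE 0.04, edgeR adjusted p = 0.34). When the test asked for a fold above 1.5, the fall of MYCN did not pass (edgeR adjusted p = 1). MYCN shares exonic sequence with the antisense gene MYCNOS, so its reads are uncertain to that extent.

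**Figure D1:**
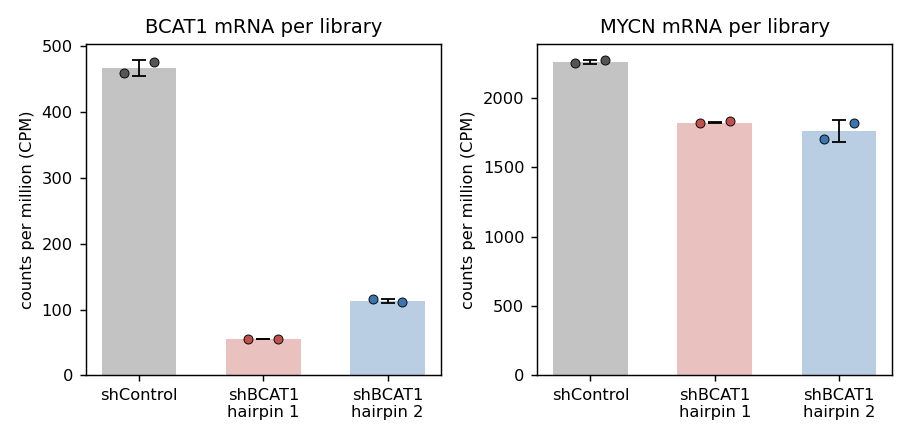
BCAT1 and MYCN mRNA per library in CPM. Points are libraries, bars are group means and error bars are SD of 2 libraries; BCAT1 means are 467, 55.5 and 113 CPM, and MYCN means are 2260, 1820 and 1760 CPM.

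The main comparison asked which transcripts differ between cells with either BCAT1 hairpin and control cells. SLC7A11, the transporter subunit that brings cystine into the cell, showed the largest rise among the genes that qualified for naming (ENSG00000151012, chromosome 4, 138164097 to 138242349). It went from 25.7 ± 0.48 CPM in control cells to 149 ± 3.9 with hairpin 1 and 167 ± 5.2 with hairpin 2 (SD, n = 2 each), a rise of 6.14-fold. CCL2, a monocyte chemoattractant, showed the largest fall after BCAT1 among the genes that qualified (ENSG00000108691, chromosome 17, 34255218 to 34257203), from 394 ± 27 CPM to 79 ± 3.1 and 64.5 ± 3.1, or 5.51-fold. TGM2, a protein-crosslinking transglutaminase, fell 5.43-fold, from 162 ± 4.5 CPM to 26.7 ± 0.78 and 33.2 ± 0.8. The edgeR adjusted p-values of these genes were 2.2e-08 for SLC7A11, 5.3e-08 for CCL2 and 1.9e-08 for TGM2. Each gene named in this comparison by size of change lay beyond both control libraries in all 4 knockdown libraries, as the naming rule required.

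In all, 9361 of 18734 tested genes (50%) passed in edgeR at an adjusted p under 0.05, with 4419 higher and 4942 lower in the knockdown cells. Their median absolute log2 fold change was 0.46, and 1034 changed by over 2-fold, 594 upwards and 440 downwards. The count depended on the size asked for: with a fold threshold of 1.5, 1039 genes passed. It also carried a trend with GC content. In simulated counts with such a trend and only 200 changed genes, 94.6% of uncorrected calls were false. That share depends on how few genes changed there, so it does not carry over to this count. Of 13829 protein-coding genes, 8475 were called without correction and 7757 with it, and 5876 were called in both with the same direction.

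After SLC7A11, the genes with the largest rises included POMK, a kinase acting on dystroglycan sugars, which rose 5.86-fold (log2 fold change 2.55, SE 0.14, edgeR adjusted p = 3.8e-06). HTR3B and HTR3A, subunits of a serotonin-gated ion channel, rose by 2.01 (SE 0.12) and 1.84 (SE 0.18) on the log2 scale. Both rose more with hairpin 1 (3.26 and 2.53) than with hairpin 2 (0.77 and 1.14). LMLN, a metallopeptidase, rose by 1.92 (SE 0.11), and DYNLRB1, a light chain of dynein, rose by 1.89 (SE 0.1). TBX20, a T-box transcription factor, rose by 1.7 (SE 0.13), and NCR3LG1, a ligand of a natural killer cell receptor, by 1.67 (SE 0.1). The edgeR adjusted p from HTR3B to NCR3LG1 ran from 3.8e-06 for DYNLRB1 to 6.3e-05 for HTR3A. The remaining rises, those of CHIC1 (1.77, SE 0.43, edgeR adjusted p = 0.0087) and the corepressor LCOR (1.69, SE 0.56, edgeR adjusted p = 0.034), depended on control libraries that were far apart. CHIC1 stood at 2.01 and 8.78 CPM in the controls and LCOR at 14.2 and 1.78 CPM. Leaving out replicate 1 or replicate 2 of the control gave 1.06 and 3.18 for CHIC1, both hairpins against control, and 3.85 and 0.86 for LCOR, both hairpins against control. The LCOR call was lost with no low-count filter, in DESeq2 and without any knockdown library.

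Among the falls, LRRC55, an auxiliary subunit of potassium channels, dropped 4.32-fold (log2 fold change −2.11, SE 0.08, edgeR adjusted p = 1.3e-06). The cytokine IL32 changed by −1.91 (SE 0.1), PLAU, the urokinase plasminogen activator, by −1.88 (SE 0.07), and BASP1, a membrane protein of growing axons, by −1.77 (SE 0.04). RAB7B, a small GTPase of endosomes, changed by −1.75 (SE 0.06), and the tetraspanin CD82 by −1.67 (SE 0.08). TMEM35A (−1.7, SE 0.13) and SFT2D3 (−1.69, SE 0.13) owed their place to hairpin 1. With hairpin 2, TMEM35A stood at 10.3 ± 0.98 CPM against 13.2 ± 0.46 in control cells (edgeR adjusted p = 0.063), and SFT2D3 at 7.06 ± 0.1 against 8.43 ± 0.071 (edgeR adjusted p = 0.17). Reads of SLC7A11, LMLN, TGM2, IL32, PLAU, BASP1, SFT2D3 and CD82 are uncertain in part, because their exons overlap those of another annotated gene.

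Transcripts of the cytosolic ribosome were lower as a group with BCAT1 knockdown. Of 71 measured ribosomal protein genes, 68 fell and 0 rose (70 and 0 adjusted over the list alone), with a median log2 fold change of −0.45 (camera adjusted p = 1.2e-16; adjusted p = 0.17 with an estimated correlation). RPL29 fell 1.71-fold, RPS10 1.68-fold and RPS27 1.65-fold. Nuclear genes of oxidative phosphorylation moved the same way: 47 of 55 fell and 1 rose, as they did adjusted over the list alone (median −0.37, camera adjusted p = 3.5e-09; adjusted p = 0.17 with an estimated correlation). Examples were COX4I1 (−0.49, SE 0.03), NDUFB8 (−0.57, SE 0.04) and UQCRQ (−0.59, SE 0.04), subunits of respiratory complexes. Of 31 proteasome subunits 23 fell and 0 rose, with the same counts adjusted over the list alone (median −0.27, camera adjusted p = 0.00016; adjusted p = 0.19 with an estimated correlation), among them PSMC1 (−0.8), PSMD13 (−0.47) and PSMD4 (−0.42). Ribosomal protein genes have many processed pseudogenes, and RPS10, COX4I1, NDUFB8, UQCRQ, PSMC1 and PSMD13 overlap other genes, so their reads are uncertain in part. The 13 mitochondrially encoded mRNAs had a median of 0, with 2 higher and 3 lower, also adjusted over the list alone (camera adjusted p = 0.99).

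Target genes of MYC and MYCN fell more often than they rose. Of 63 such genes 36 fell and 8 rose (38 and 9 adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.002; adjusted p = 0.17 with an estimated correlation). With hairpin 1 alone the list did not pass. The nucleolar protein NOLC1 went from 408 ± 11 CPM to 183 ± 0.31 with hairpin 1 and 308 ± 3.6 with hairpin 2. NME1, a nucleoside diphosphate kinase whose reads can be split with the NME1-NME2 read-through, changed by −0.87 (SE 0.05), while UTP20, a ribosome assembly factor, rose by 0.61 (SE 0.04), a call lost after correction for GC content and length. Ribosome biogenesis factors as a list did not pass, with 11 higher and 18 lower of 50, the same counts adjusted over the list alone (median −0.05, camera adjusted p = 0.37), although after correction for GC content and length they passed downwards (adjusted p = 0.22 with an estimated correlation). Regulators of N-Myc stability, a list holding both stabilizing and destabilizing proteins, were shifted upwards. Of 34, 17 rose and 4 fell (17 and 5 adjusted over the list alone), with a median of 0.23 (camera adjusted p = 0.038; adjusted p = 0.25 with an estimated correlation). SET, an inhibitor of the phosphatase PP2A, and the deubiquitinase USP28 both rose 1.58-fold.

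Genes of the ATF4 and amino acid starvation response rose over both hairpins, though not as a list with hairpin 2 alone. Of 41 measured, 31 rose and 1 fell (32 and 1 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 2.8e-06; adjusted p = 0.17 with an estimated correlation). ALDH1L2, a mitochondrial folate enzyme, rose from 50.9 ± 2.7 CPM to 115 ± 5 and 101 ± 3.4, and EPRS1, the glutamyl-prolyl-tRNA synthetase, rose 1.65-fold. ASNS, asparagine synthetase, rose over both hairpins by 0.55 (SE 0.04, edgeR adjusted p = 9.9e-06), but stood at 229 ± 7.8 CPM with hairpin 1 and 93.7 ± 0.76 with hairpin 2, against 99.8 ± 1.9 in control cells. The unfolded protein response list moved in the other direction, with 18 of 32 lower and 7 higher, as also adjusted over the list alone (median −0.3, camera adjusted p = 0.046; adjusted p = 0.4 with an estimated correlation). Within it, PDIA4, a disulfide isomerase, and MANF, a secreted factor of the endoplasmic reticulum, changed by −0.74 and −0.89 on the log2 scale, whereas EIF2AK3, the stress kinase PERK, rose by 1.22. Cholesterol synthesis genes fell in 14 of 26 cases and rose in 5, with the same counts adjusted over the list alone (median −0.17, camera adjusted p = 0.038; adjusted p = 0.28 with an estimated correlation), as for FDPS (−0.84), EBP (−0.83) and DHCR7 (−0.58). Exons of ALDH1L2, EIF2AK3 and FDPS overlap other genes, so their reads are uncertain in part.

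Inflammatory genes under NF-kB fell over both hairpins, led by CCL2, though not as a list with hairpin 1 alone. Of 20 measured 11 fell and 1 rose, with the same counts adjusted over the list alone (median −0.73, camera adjusted p = 0.00086; adjusted p = 0.17 with an estimated correlation). NFKBIA, the inhibitor that NF-kB itself induces, fell 2.41-fold, and the chemokine CXCL1 fell 2.09-fold. Genes of the mesenchymal neuroblastoma state fell in 26 of 43 cases and rose in 6 (26 and 8 adjusted over the list alone), with a median of −0.22 (camera adjusted p = 0.012; adjusted p = 0.19 with an estimated correlation). The collagens COL6A2 and COL3A1 changed by −1.12 and −0.93, and the galectin LGALS1 by −1. The list of fibroblast markers, which these neuroblastoma cells also express, had 8 of 10 lower and 0 higher (10 and 0 adjusted over the list alone; median −0.5, camera adjusted p = 0.00034; adjusted p = 0.17 with an estimated correlation). THY1 (−0.83, in overlap with another gene), TAGLN (−1.59) and FBLN1 (−0.67) were among them, and all 10 had at least 10 CPM in control cells. Markers of epithelium (3 higher and 2 lower of 9) and of Schwann cell precursors and melanocytes (0 higher and 1 lower of 5) did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.94 and 0.65).

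Neuronal differentiation genes were raised on balance, with 20 of 41 higher and 8 lower (21 and 8 adjusted over the list alone; median 0.32, camera adjusted p = 0.031; adjusted p = 0.23 with an estimated correlation), a rise carried by hairpin 1. MAP2, a dendritic microtubule protein, rose by 1.03 (SE 0.04), while the neuropeptide GAL and the neuronal enolase ENO2 changed by −1.02 and −0.73. DNA repair genes rose in 14 of 30 cases and fell in 5, as also adjusted over the list alone (median 0.19, camera adjusted p = 0.038; adjusted p = 0.46 with an estimated correlation), among them the double-strand break genes RAD50 (0.94), ATM (1) and PRKDC (0.63), with RAD50 and ATM overlapping other genes. Replication-dependent histone genes fell in 7 of 17 cases and rose in 0, with the same counts adjusted over the list alone (median −0.29, camera adjusted p = 0.047; adjusted p = 0.28 with an estimated correlation), as for H1-2 (−1.33), H2BC12 (−0.78) and H2BC11 (−0.71). Lists of p53 targets (10 higher and 11 lower of 33, median −0.08 but mean 0.09), apoptosis regulators (7 higher and 12 lower of 31) and the mTORC1 and PI3K pathway (16 and 16 of 43; 17 and 17 adjusted over the list alone) did not pass (camera adjusted p = 0.88, 0.31 and 0.7). Counts for p53 targets and apoptosis regulators were the same adjusted over the list alone. Of the 42 lists, 14 passed in camera, 4 upwards and 10 downwards, 33 passed in fry, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.17.

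Fold changes in this comparison also followed GC content and transcript length. Across 13829 protein-coding genes, which are not independent replicates, the Spearman correlation of log2 fold change was −0.43 with GC content and 0.3 with length. After a per-library correction for both, the medians were −0.36 for ribosomal proteins, −0.28 for oxidative phosphorylation, −0.2 for the proteasome, 0.3 for the ATF4 list, −0.62 for NF-kB, 0.21 for neuronal differentiation, −0.23 for mesenchymal genes, −0.35 for the unfolded protein response, −0.23 for cholesterol synthesis and −0.35 for fibroblast markers, and these lists passed in camera, but not with an estimated correlation (adjusted p from 0.22 to 0.32). MYC and MYCN targets lost their call over both hairpins to the correction, with a median of −0.12 (camera adjusted p = 0.1, against 0.0038 in the same genes without correction). With hairpin 2 alone they still passed after it (median −0.18, camera adjusted p = 0.0072, or 0.22 with an estimated correlation), and with hairpin 1 they did not (−0.02, 0.87). Over both hairpins, N-Myc stability regulators (0.07, camera adjusted p = 0.088), histones (−0.19, 0.13) and DNA repair genes (−0.01, 0.86) also did not pass after correction. Those lists already missed the threshold in the same genes without correction (camera adjusted p = 0.052, 0.072 and 0.052). So did the unfolded protein response (0.07) and cholesterol synthesis (0.058), which passed in these genes only after correction. Other lists that passed only after correction were ribosome biogenesis (median −0.18, camera adjusted p = 0.00087), S phase (−0.14, 0.0033), G2/M (−0.19, 0.0033) and amino acid transporters (0.24, 0.043), with adjusted p from 0.22 to 0.26 with an estimated correlation. Of the 13829 genes, 8475 were called without correction and 7757 with it. For single genes, 5746 of the 8083 calls that had a corrected value kept their direction and their call, and 260 were called in the opposite direction. Named genes whose log2 fold change over both hairpins shrank by over 1.5 times, but which stayed called, were RPL29 (corrected −0.48), EPRS1 (0.39), DHCR7 (−0.29), COX4I1 (−0.29), NDUFB8 (−0.36), H2BC12 (−0.49), PRKDC (0.23), PSMD4 (−0.24), FBLN1 (−0.32), TK1 (−0.17), PHOX2A (−0.39), NME4 (−0.53), APRT (−0.69), PPAT (0.19) and EEF1D (−0.36). Calls of UTP20 (0.08), EIF3A (0.07) and ATAD2 (−0.01) over both hairpins ended.

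**Figure D2:**
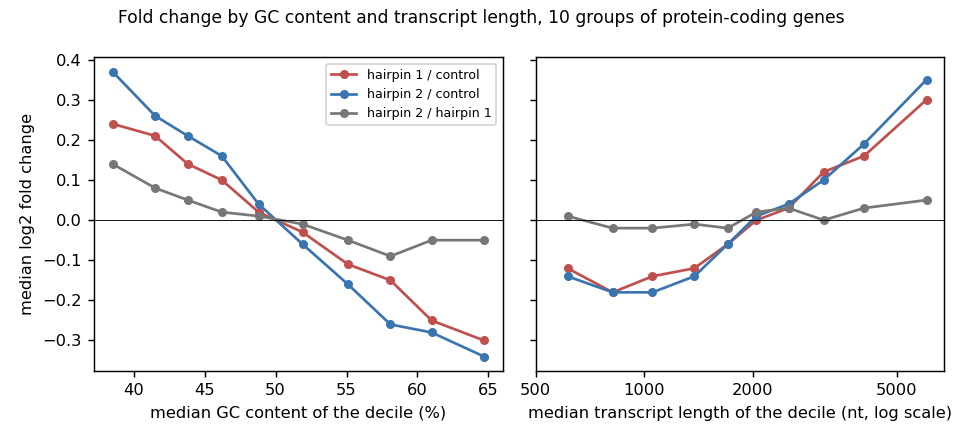
Median log2 fold change of protein-coding genes in 10 groups of rising GC content (left, in percent) and of rising transcript length (right, in nucleotides on a log axis), for each hairpin against control and for hairpin 2 against hairpin 1. With either hairpin, genes of low GC content and long transcripts lie above 0 and genes of high GC content and short transcripts below; the Spearman correlations with GC content are −0.3 for hairpin 1 and −0.45 for hairpin 2.

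Hairpin 1 against control asked the same of the deeper knockdown. HTR3B rose from 1.84 ± 0.12 CPM to 17.7 ± 1.4 (SD, n = 2), or 9.57-fold, and INHBE, a subunit of activin E, rose from 2.06 ± 0.38 CPM to 17.1 ± 0.51, or 8.32-fold. POMK (7.59-fold), the synaptic protein NPTX1 (6.12-fold) and SLC7A11 (5.8-fold) rose as well, with edgeR adjusted p-values from 5.6e-08 for SLC7A11 to 2.7e-06 for NPTX1. SFT2D3 and TMEM35A fell 8.73-fold and 8.18-fold, TAGLN, an actin-binding protein, fell 7.06-fold, and TENT5C, a poly(A) polymerase, fell 6.21-fold (edgeR adjusted p between 3.1e-07 for TENT5C and 3.2e-06 for TMEM35A). As the naming rule required, every gene named here lay beyond both controls in both libraries. The read-through gene HSPE1-MOB4 was at 0 counts in both hairpin 1 libraries and at 12.4 and 3.08 CPM in the controls, at least 33-fold lower from the lower control library and a floor of 3 counts per library (edgeR adjusted p = 0.00073). It shares its exons with HSPE1 and MOB4, so its reads are uncertain, as in part are those of SFT2D3 and TAGLN.

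With hairpin 1, 9199 genes passed in edgeR, 4526 higher and 4673 lower, and 1695 of them changed by over 2-fold (841 upwards, 854 downwards). The ATF4 list rose in 32 of 41 cases and fell in 2, the same counts adjusted over the list alone (median 0.59, camera adjusted p = 8.5e-09; adjusted p = 0.18 with an estimated correlation). ASNS rose by 1.2 (SE 0.04) on the log2 scale. Neuronal differentiation genes rose in 25 of 41 cases and fell in 5 (28 and 5 adjusted over the list alone; median 0.62, camera adjusted p = 4.7e-05; adjusted p = 0.18 with an estimated correlation), with MAP2 up 3.28-fold. G2/M and mitosis genes rose in 36 of 67 cases and fell in 9 (38 and 11 adjusted over the list alone; median 0.15, camera adjusted p = 0.0058; adjusted p = 0.38 with an estimated correlation), for example the microtubule regulator CKAP5 (0.96). The N-Myc stability regulators (20 higher and 4 lower of 34, 21 and 6 adjusted over the list alone; median 0.25, camera adjusted p = 0.0058) and DNA repair genes (19 higher and 3 lower of 30, 20 and 3 adjusted over the list alone; median 0.24, camera adjusted p = 0.0038) also rose. With an estimated correlation these became adjusted p = 0.19 and adjusted p = 0.38. After correction for GC content and length, which correlated with the fold changes at −0.3 and 0.23 across genes, the G2/M genes (median 0.13) and the DNA repair genes (0.14) no longer passed, nor did the N-Myc stability regulators (0.19).

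Ribosomal protein genes fell with hairpin 1 in 68 of 71 cases and rose in 0, as also adjusted over the list alone (median −0.43, camera adjusted p = 8e-14; adjusted p = 0.18 with an estimated correlation). Oxidative phosphorylation genes fell in 38 of 55 cases and rose in 2, and proteasome subunits fell in 20 of 31 and rose in 2, both with the same counts adjusted over the list alone (medians −0.34 and −0.25, camera adjusted p = 1.4e-05 and 0.0025; adjusted p = 0.18 and adjusted p = 0.25 with an estimated correlation). Corrected for GC content and length, these medians were −0.31, −0.18 and −0.16. Fibroblast markers fell in 9 of 10 cases (10 adjusted over the list alone; median −0.72, camera adjusted p = 4.6e-05; adjusted p = 0.18 with an estimated correlation), TAGLN 7.06-fold. Mesenchymal genes fell in 23 of 43 cases and rose in 9 (24 and 9 adjusted over the list alone; median −0.35, camera adjusted p = 0.0044; adjusted p = 0.18 with an estimated correlation). Histone genes fell in 9 of 17 and rose in 0, and genes of the unfolded protein response fell in 19 of 32 and rose in 7, the same counts adjusted over the list alone (medians −0.54 and −0.34, camera adjusted p = 0.0023 and 0.038; adjusted p = 0.18 and adjusted p = 0.38 with an estimated correlation). NF-kB genes did not pass with hairpin 1, with 6 higher and 7 lower of 20 (6 and 10 adjusted over the list alone; median −0.2, mean −0.02, camera adjusted p = 0.44). MYC and MYCN targets did not pass either, with 12 higher and 27 lower of 63 (13 and 29 adjusted over the list alone; median −0.08, camera adjusted p = 0.25).

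With hairpin 2, the comparison with control gave a partly different set of leading genes. CCN2, a matricellular protein (ENSG00000118523, chromosome 6, 131948176 to 131951373), rose from 3.88 ± 0.17 CPM to 29.7 ± 2.2 (SD, n = 2), or 7.65-fold, followed by SLC7A11 (6.49-fold), LMLN (5.13-fold), POMK (4.52-fold) and LCOR (4.21-fold). ICAM1, a leukocyte adhesion molecule (ENSG00000090339, chromosome 19, 10270835 to 10286615), fell from 10.1 ± 0.19 CPM to 1.41 ± 0.14, or 7.13-fold. CCL2 fell 6.11-fold, TNFRSF9, a receptor of the tumour necrosis factor family, 5.06-fold, TGM2 4.87-fold and LRRC55 4.68-fold. The edgeR adjusted p of these genes ran from 9.2e-08 for SLC7A11 to 1.2e-05 for POMK, except 0.022 for LCOR, whose call was lost without either hairpin 2 library, with no low-count filter and in DESeq2. Without replicate 1 or replicate 2 of the control, LCOR, hairpin 2 against control, was 4.24 and 1.25. Reads of CCN2 and ICAM1 are uncertain in part because of overlapping genes. As the naming rule required, every gene named here lay beyond both controls in both hairpin 2 libraries.

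With hairpin 2, 9236 genes passed in edgeR, 4486 higher and 4750 lower, and 1387 of them changed by over 2-fold (847 upwards, 540 downwards). All 12 lists that passed in camera were lower. The ATF4 list did not pass, with 17 higher and 8 lower of 41 (17 and 9 adjusted over the list alone; median 0.07, camera adjusted p = 0.29), nor did neuronal differentiation, with 8 higher and 17 lower of 41 (8 and 19 adjusted over the list alone; median −0.22, camera adjusted p = 0.16). Fibroblast markers (median −0.19, camera adjusted p = 0.15), mesenchymal genes (−0.02, 0.35), DNA repair genes (0.13, 0.35) and N-Myc stability regulators (0.06, 0.53) did not pass with this hairpin either. Inflammatory genes under NF-kB fell in 15 of 20 cases and rose in 0 (17 and 0 adjusted over the list alone; median −1.24, camera adjusted p = 1.1e-07; adjusted p = 0.15 with an estimated correlation), NFKBIA 3.24-fold and CXCL1 2.84-fold. G2/M genes fell in 39 of 67 cases and rose in 10 (41 and 10 adjusted over the list alone; median −0.27, camera adjusted p = 7.1e-05; adjusted p = 0.29 with an estimated correlation). MYBL2, a transcription factor of the cell cycle, fell from 244 ± 1.6 CPM to 99.2 ± 2.6, and the phosphatase CDC25B fell 1.92-fold, while CKAP5 rose 1.4-fold. S phase genes fell in 35 of 59 cases and rose in 5 (37 and 5 adjusted over the list alone; median −0.2, camera adjusted p = 0.00045; adjusted p = 0.15 with an estimated correlation), with TK1, thymidine kinase, down 1.84-fold and TYMS, thymidylate synthase, down 1.61-fold, while ATAD2, a chromatin ATPase, rose 1.34-fold. MYC and MYCN targets fell in 42 of 63 cases and rose in 10 (43 and 10 adjusted over the list alone; median −0.28, camera adjusted p = 9.7e-05; adjusted p = 0.15 with an estimated correlation), NME1 2.35-fold.

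Ribosomal protein genes fell with hairpin 2 in 68 of 71 cases and rose in 0 (70 and 0 adjusted over the list alone; median −0.46, camera adjusted p = 5.6e-16; adjusted p = 0.15 with an estimated correlation). Oxidative phosphorylation genes fell in 49 of 55 and rose in 0 (52 and 1 adjusted over the list alone; median −0.38, camera adjusted p = 4.9e-10; adjusted p = 0.15 with an estimated correlation) and proteasome subunits in 23 of 31, with 1 higher (25 and 1 adjusted over the list alone; median −0.29, camera adjusted p = 7.1e-05; adjusted p = 0.18 with an estimated correlation). PSMC1 fell 2.49-fold. Nucleotide synthesis genes fell in 14 of 24 cases and rose in 2, with APRT (−0.84) and NME4 (−0.82) lower and PPAT (0.4) higher, and secreted factors of senescence in 16 of 22 with 2 higher, among them PLAU, IGFBP7 and MMP14, both with the same counts adjusted over the list alone (medians −0.24 and −0.45, camera adjusted p = 0.005 and 0.00075; adjusted p = 0.36 and adjusted p = 0.17 with an estimated correlation). Adrenergic circuitry genes fell in 18 of 32 and glycolysis genes in 14 of 22, with 5 higher in each, also adjusted over the list alone (medians −0.22 and −0.23, camera adjusted p = 0.033 and 0.047; adjusted p = 0.38 and adjusted p = 0.41 with an estimated correlation). The tyrosine kinase RET, the transcription factor PHOX2A and the glycolytic enzyme ENO1 fell 1.57-fold, 1.62-fold and 1.56-fold. Translation factors fell in 18 of 35 cases and rose in 6 (19 and 6 adjusted over the list alone; median −0.16, camera adjusted p = 0.041; adjusted p = 0.29 with an estimated correlation), with EEF1B2 (−0.48) and EEF1D (−0.67) lower and EIF3A (0.44) higher. Exons of ATAD2, TYMS, NME4, IGFBP7, PHOX2A, ENO1, EEF1B2 and EEF1D overlap other genes, so their reads are uncertain in part. Hairpin 2 fold changes correlated at −0.45 with GC content and 0.28 with length across genes, and after correction the medians of ribosomal proteins, oxidative phosphorylation, NF-kB, G2/M and senescence factors were −0.35, −0.35, −1.06, −0.47 and −0.23. Senescence factors lost their call to the correction (camera adjusted p = 0.2, against 0.0021 in the same genes without correction). Adrenergic circuitry, glycolysis and translation factors did not pass (camera adjusted p = 0.19, 0.34 and 0.057), nor did they in the same genes without correction (0.059, 0.069 and 0.069). Lists that passed only after correction were ribosome biogenesis (−0.2, camera adjusted p = 3e-05), the unfolded protein response (−0.24, 0.021), cholesterol synthesis (−0.24, 0.022) and, upwards, the ATF4 list (0.12, 0.022), with adjusted p from 0.22 to 0.39 with an estimated correlation.

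**Figure D3:**
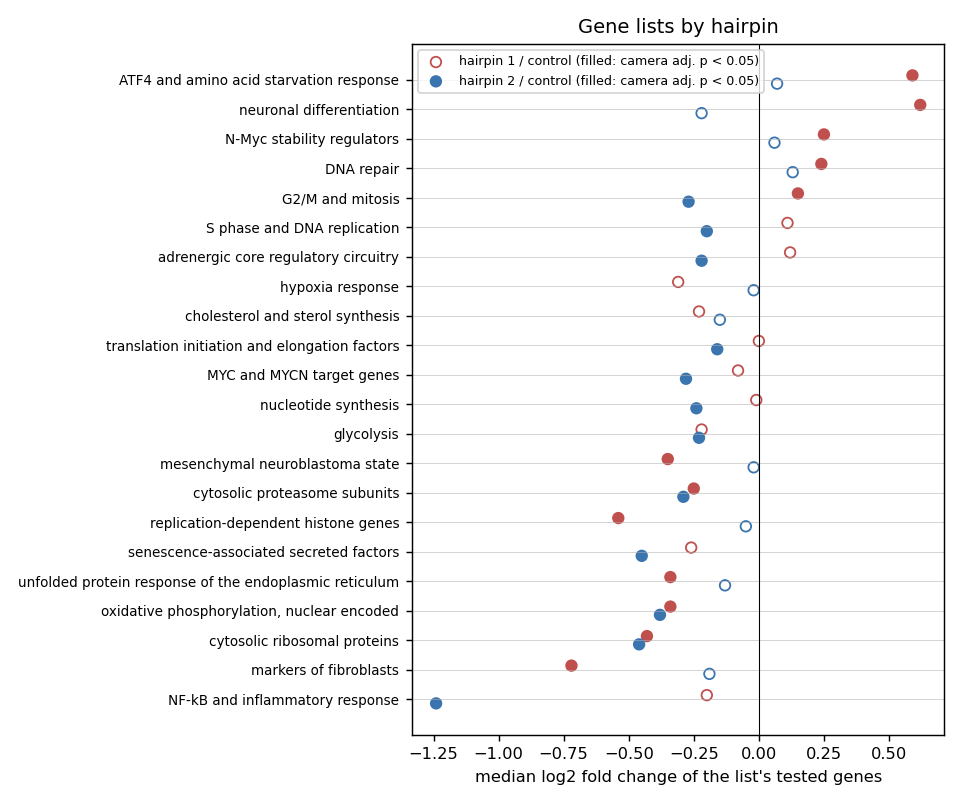
Median log2 fold change of each gene list with hairpin 1 and with hairpin 2 against control, for the lists that passed in camera in any comparison. Filled points passed at an adjusted p under 0.05; ribosomal proteins lie at −0.43 and −0.46, NF-kB genes at −0.2 and −1.24, and G2/M genes at 0.15 and −0.27.

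Genes that changed the same way with both hairpins included BCAT1, SLC7A11, POMK, CCL2, TGM2, LRRC55 and MYCN. PDIA4 and MANF fell alike with each hairpin, PDIA4 to 496 ± 8.7 and 497 ± 0.0056 CPM from 827 ± 4.1 in control cells, and MANF to 68.1 ± 2.6 and 66.9 ± 1.4 CPM from 125 ± 2.5. SET rose to 800 ± 6.7 and 771 ± 6.7 CPM from 498 ± 10, and ATM rose 2-fold with each. In all, 5041 genes passed with both hairpins in the same direction, 2430 higher and 2611 lower, and 2759 of the 5041 did not differ between the hairpins in edgeR. Independent lists of these sizes would share 1084 higher and 1185 lower genes. In 20 simulations of unchanged groups against these controls, at most 4 genes were called with both hairpins in the same direction and 0 in opposite directions. No gene changed in these simulations, so few could pass the adjusted threshold. Those counts are therefore no chance baseline for the 5041 shared calls. Fold changes of the hairpins correlated at 0.476 across genes, which are not independent replicates, where shared controls alone gave 0.503. Their covariance was 0.2832 against 0.0463 in the simulation, a difference of 0.2369. The simulated groups varied only by the spread between replicates. A shift common to both control libraries would therefore stay in this difference. Part of the excess of shared calls over independent lists may come from the shared controls, which were too few to split.

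Hairpin 2 against hairpin 1 asked where the hairpins differed. CCN2 stood at 1.64 ± 0.012 CPM with hairpin 1 and 29.7 ± 2.2 with hairpin 2 (SD, n = 2), a difference of 4.17 on the log2 scale (SE 0.12, edgeR adjusted p = 1.6e-07). ANKRD1, a cardiac and muscle ankyrin repeat protein, ACTA2, smooth muscle actin, and the muscarinic receptor CHRM1 were also higher with hairpin 2, by 3.53 (SE 0.15), 3.27 (SE 0.09) and 3.07 (SE 0.18). All of CCN2, ANKRD1, ACTA2 and CHRM1 fell with hairpin 1 and rose with hairpin 2 against control. PTGS2, the inducible cyclooxygenase, rose with hairpin 1 to 19.6 ± 1.4 CPM and fell with hairpin 2 to 2.52 ± 0.33, from 5.85 ± 0.48 in control cells (difference −2.96, SE 0.14). ICAM1 (−2.95), INHBE (−2.88), the adenosine receptor ADORA2A (−2.87) and XKR7 (−2.63) were lower with hairpin 2 than with hairpin 1. The edgeR adjusted p of these genes was at most 2.4e-05, the value of XKR7. In each the libraries of the hairpins did not overlap, as the naming rule required. HSPE1-MOB4 was at least 89-fold higher with hairpin 2, from the lower hairpin 2 library and a floor of 3 counts per library, given 0 counts with hairpin 1. Reads of CCN2, ACTA2, CHRM1, ICAM1, ADORA2A and HSPE1-MOB4 are uncertain because of overlapping genes.

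Between the hairpins 8650 genes differed in edgeR, 4290 higher and 4360 lower with hairpin 2, and 1861 by over 2-fold (1066 and 795). Of the genes called with both hairpins, 1074 went in opposite directions, 577 of them higher with hairpin 1 and 497 higher with hairpin 2. Independent lists would share 2267 such genes. G2/M and mitosis genes were lower with hairpin 2 in 57 of 67 cases and higher in 3 (58 and 3 adjusted over the list alone; median −0.48, camera adjusted p = 3.5e-12; adjusted p = 0.17 with an estimated correlation). NF-kB genes were lower in 18 of 20 and S phase genes in 43 of 59, the same counts adjusted over the list alone (medians −1.02 and −0.31, camera adjusted p = 8.3e-08 and 2.7e-07; adjusted p = 0.13 for each with an estimated correlation). The ATF4 list was lower in 29 of 41 cases and higher in 4 (30 and 5 adjusted over the list alone; median −0.47, camera adjusted p = 7.2e-06; adjusted p = 0.2 with an estimated correlation), and neuronal genes were lower in 28 and higher in 6 of 41, the same adjusted over the list alone (median −0.88, camera adjusted p = 3.7e-06; adjusted p = 0.13 with an estimated correlation). For ASNS and MAP2 the difference was −1.29 and −1.36.

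Differences also passed for 7 other lists. MYC and MYCN targets were lower with hairpin 2 in 29 of 63 cases (31 adjusted over the list alone; median −0.12, camera adjusted p = 0.0066), N-Myc stability regulators in 18 of 34 (18; −0.16, 0.029), adrenergic circuitry genes in 18 of 32 (18; −0.19, 0.0066) and nucleotide synthesis genes in 13 of 24 (14; −0.16, 0.0092). With an estimated correlation these gave adjusted p = 0.2, adjusted p = 0.24, adjusted p = 0.28 and adjusted p = 0.28. Histone genes were higher with hairpin 2 in 8 of 17 cases (8 adjusted over the list alone; median 0.52, camera adjusted p = 0.006), fibroblast markers in 7 of 10 (7; 0.42, 0.0066) and hypoxia genes in 11 of 21 (13; 0.44, 0.024). With an estimated correlation these gave adjusted p = 0.22, adjusted p = 0.23 and adjusted p = 0.24. Hypoxia genes named by the rule, which picked them by their p over both hairpins, were HILPDA (0.65), EGLN3 (0.44) and ANGPTL4 (0.54, edgeR adjusted p = 0.059). They need not be the hypoxia genes that differed most between the hairpins. HILPDA and ANGPTL4 overlap other genes. Ribosomal proteins (median −0.04, camera adjusted p = 0.5) and proteasome subunits (median −0.04, camera adjusted p = 0.29) did not pass in this comparison. The difference between hairpins correlated at −0.12 with GC content and 0.03 with length across genes. After correction for both, adrenergic circuitry (median −0.22) and N-Myc stability regulators (−0.16) no longer passed (camera adjusted p = 0.052 for each, against 0.016 and 0.055 in the same genes without correction), and DNA repair genes passed (−0.22, camera adjusted p = 0.0079; adjusted p = 0.28 with an estimated correlation).

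**Figure D4:**
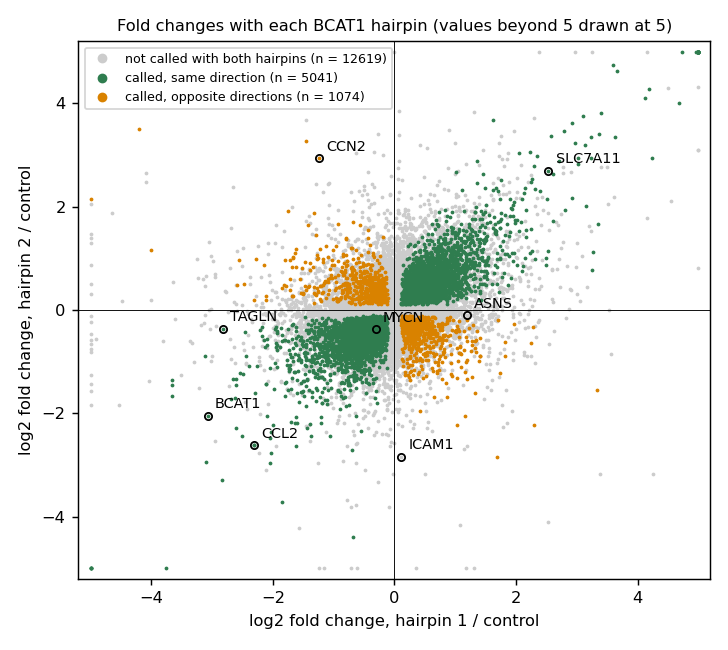
Log2 fold change against control with hairpin 1 (horizontal) and hairpin 2 (vertical), a point per tested gene, with values beyond 5 drawn at 5. Green points passed with both hairpins in the same direction (5041 genes) and orange points in opposite directions (1074 genes); named genes are circled.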

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

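The tests of the hairpin-associated heptamers, of knockdown depth, of the GC and length correction and of the library slopes were chosen after the result was seen; the pseudogene test and the tests of list members without heptamer matches were written before theirs, although the number of lists lost without such genes was known by then.

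The hairpins differed by a direct test of hairpin 2 against hairpin 1, which called 8650 genes. In the comparisons of each hairpin with control, 1074 genes were called in opposite directions. All of these also differed in the direct test. This follows nearly by construction, because that test takes the difference of these fold changes, and adds no separate evidence. BCAT1 itself differed by 1.03 on the log2 scale. Among the other genes named in the report, 64 also differed. HSPE1-MOB4 was at least 89-fold higher with hairpin 2. Log2 differences were 4.17 for CCN2, 3.53 for ANKRD1, 3.27 for ACTA2, 3.07 for CHRM1, −2.96 for PTGS2, −2.95 for ICAM1, −2.88 for INHBE, −2.87 for ADORA2A and −2.63 for XKR7. Median differences of lists were −0.48 for G2/M, −0.31 for S phase, −0.88 for neuronal differentiation, −0.47 for the ATF4 response, −1.02 for NF-kB, −0.12 for MYC and MYCN targets, −0.16 for N-Myc stability regulators, −0.19 for adrenergic circuitry, −0.16 for nucleotide synthesis, 0.44 for hypoxia, 0.52 for histones and 0.42 for fibroblast markers.

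The first pattern weighed was the number of genes that differ between the hairpins. A response that grows steadily with the depth of BCAT1 knockdown, as the only cause, is argued against by 4405 genes. They changed with the shallower hairpin 2 and by the direct test lay beyond hairpin 1 in the direction of that change. A false share of 9.2%, taken from simulated counts of both hairpins against control, would give 796 (4233 against 776 with GC and length corrected, at the same share). That simulation held 200 changed genes and independent replicates, so 796 and 776 are rough guides, not baselines for this comparison. Both tests behind the 4405 genes used the same hairpin 2 libraries, so a shift common to those libraries would pass both. Such a shift, and a response that does not grow steadily with depth, were not tested and stay open. Silencing through 3′ UTR matches may contribute: given 3′ UTR length and GC, genes holding AGCAGTA differed from genes without it by a mean log2 fold change of −0.228 with hairpin 1 (z −15.3; −0.011 with hairpin 2), and genes holding TTGCCCA by −0.113 with hairpin 2 (z −11; 0.012 with hairpin 1), where the largest permuted z was 4.9 and 5.3. Without that adjustment their medians, −0.018 with hairpin 1 and 0.036 with hairpin 2, lay above those of genes with neither hexamer (−0.039 and −0.062), while their medians for hairpin 2 against hairpin 1 were 0.201 and −0.066, against −0.001 in all searched genes. Both heptamers occur in the BCAT1 coding sequence, as do 6.6% of all heptamers, but the hairpin sequences are not given in the sources used here, so the match to a hairpin strand is a hypothesis. 3′ UTR matches to the hexamers GCAGTA and TGCCCA as the whole cause are argued against. Of the 6146 searched genes with neither hexamer, 50.9% still differed. Matches in coding sequence and to other heptamers were not removed, so they stay open. Effects downstream of such silencing or of BCAT1 stay open too, as untested.

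The next pattern was the fall of ribosomal protein, respiratory chain and proteasome mRNAs with both hairpins. The GC and length trend as the whole cause is argued against by corrected medians of −0.36, −0.28 and −0.2, each still past the camera threshold, though not with an estimated correlation (adjusted p = 0.22, 0.22 and 0.26). Reads moved to pseudogenes are argued against by the sum of parent and pseudogene counts, which changed by −0.45 on the log2 scale. The origin of the GC trend cannot be told apart between library preparation and the cells, because the slopes of control and knockdown libraries were separated by 0.15 (log2 per 10% GC) and so follow the groups. A response to lower BCAT1, and a response to hairpin expression that differs from that of the control hairpin, may each be part of the pattern and were not tested.

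The last pattern was the lists that differ between the hairpins. Matches to GCAGTA or TGCCCA in the 3′ UTRs of the lists' own genes, as the whole cause, are argued against by members with neither hexamer. Their median differences were −0.47 for G2/M, −0.58 for the ATF4 response, −0.57 for neuronal differentiation and −0.87 for NF-kB. Each was past the camera threshold with its preset correlation among genes with neither hexamer. Different depth of BCAT1 knockdown alone, with a response that grows steadily with depth, is argued against for G2/M and NF-kB genes. Their medians with the shallower hairpin 2 (−0.27 and −1.24) lay below those with hairpin 1 (0.15 and −0.2). A shift common to the hairpin 2 libraries would give the same and was not tested. For the ATF4 list, at 0.07 with hairpin 2 and 0.59 with hairpin 1, depth may be the cause, while for neuronal genes (−0.22 and 0.62) it cannot be told apart, because the list did not pass with hairpin 2. Silencing of a few upstream regulators through such matches could also move whole lists and stays open, untested.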

How the results depend on the processing

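The GC and length correction, the same genes without it, rows with a symbol only and genes with neither hexamer were chosen after seeing the data. Of 3027 alternative values, 2846 kept their direction and their side of the threshold (counts: stayed within 1.5 times), 167 no longer passed and 1 reversed: ATAD2 went from 0.41 to −0.01 with GC and length corrected, a trend that construction removes. A fold threshold of 1.5, which asks for a larger change, gave 1039 genes changed, both BCAT1 hairpins against control, 1769 genes changed, hairpin 1 against control, 1397 genes changed, hairpin 2 against control, 1774 genes that differ between the hairpins and 369 genes changed the same way by both hairpins. There MYCN mRNA, both BCAT1 hairpins against control, no longer passed at −0.34. Genes with neither hexamer gave 3613, 3535, 3560, 3268 and 2096 of these, from fewer genes tested. For both hairpins, RLE factors gave 9355 genes, no filter 8508, the stricter filter 9037, DESeq2 7897, limma-voom 9460, summed symbols 9362, symbols only 9033 and the GC and length correction 7757. Leaving out each library in turn, where the lone library is assumed to vary like the other groups, gave 7517 to 8889 genes for both hairpins, 7725 to 8798 for hairpin 1, 7216 to 9202 for hairpin 2, 6561 to 8732 between hairpins, 3963 to 4547 shared, BCAT1 mRNA, both BCAT1 hairpins against control, at −2.59 to −2.53, MYCN at −0.36 to −0.32 and 10 to 14 lists. With the GC and length correction BCAT1 was −2.85 and MYCN −0.31, and UTP20 (0.08) and EIF3A (0.07) no longer passed. For both hairpins, 14 of the 42 lists passed in the main test. Estimated correlation left 0, fry passed 33 of the 42, and genes with GC and length but no correction gave 9, where the cause was not tested. With the replicate block, 9000, 8802, 8841 and 8218 genes were called, 4788 shared, and 11 lists passed; samples share only a number, as deviations of the same number correlated at 0.004, −0.038 and −0.033. Using only the groups compared gives no separate value for both hairpins, and the hexamer alternative none for BCAT1 or MYCN. In simulated counts 58.8% of changes of 0.5 on the log2 scale were recovered, and depth was not varied.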

Other observations

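Branched-chain amino acid genes did not move as a list with both hairpins: 12 of 34 rose and 8 fell (13 and 8 adjusted over the list alone; median 0.06, camera adjusted p = 0.37). The genes in this paragraph were chosen after their values were seen. BCAT2, the mitochondrial counterpart of BCAT1, changed by −0.21 (SE 0.07, edgeR adjusted p = 0.027), and the kinase BCKDK, which inhibits the branched-chain keto acid dehydrogenase, by −0.59. Subunits of that dehydrogenase moved apart, with BCKDHA at −0.34, BCKDHB at 0.63 and DBT at 0.6. Amino acid transporters did not pass as a list, with 12 of 20 higher and 4 lower (12 and 5 adjusted over the list alone; median 0.23, camera adjusted p = 0.1), though they passed with GC and length corrected (median 0.24, camera adjusted p = 0.043; adjusted p = 0.26 with an estimated correlation). SLC7A5, the light chain of a leucine transporter, changed by 0.86 with hairpin 1 and 0.11 with hairpin 2, with a difference of −0.75 between them.

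Heptamers were scanned in 3′ UTRs in 4 comparisons, in both directions, 16352 in each, and the pair described above was picked as the leading one for each hairpin. Others also exceeded the permuted range: among genes higher with both hairpins, GTCGCCC reached z 5.1 and CACACGC 5, where the largest permuted z was 4.9 (permutation p = 0.005, the smallest that 200 permutations can give). On the lower side of the main comparison, GCAGTAA (z −11) and AGCAGTA (z −10.6) led, where the largest permuted z was 4.8. Their effects were −0.235 and −0.228 with hairpin 1, and −0.024 and −0.011 with hairpin 2. So falls averaged over both hairpins also carry this hairpin 1 effect. The library slopes on GC (log2 per 10%) were 0.199 and 0.123 for control, −0.051 and −0.027 for hairpin 1, and −0.129 and −0.114 for hairpin 2.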
